A study of Mus musculus with 59 samples.

How the data were processed

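RNA sequencing libraries were made from homogenate medial prefrontal cortex of adult wild-type C57BL/6J mice of both sexes, with 1 library per column of the deposited table and 59 libraries in all. Per the labels, RNA was extracted with the Qiagen RNeasy Plus Micro kit, libraries were made with the Takara SMART Stranded Total RNA kit, and the authors named FastQC, HTSeq and DESeq2 and the genome build GRCm38, without versions, an aligner, an annotation release or the strand setting of the counting. The deposited values are log2 values of a scaled read count plus 1, although the table is named for raw counts. In every library 2 to the power of the value, minus 1, was a whole multiple of 1 step for each gene, within 0.0202 of a whole number. The reciprocals of the steps followed the median-of-ratios size factors of the recovered whole reads (Spearman rho 0.996 over the libraries). Whole reads were recovered by dividing by these steps and were used for depth, for the filter on low values and for some alternatives.

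Groups were taken from the titles, which give the zeitgeber time, the sex, a number for the animal and a serial number. Libraries of each group were numbered as replicates by the run of 12 serial numbers they fell in, and the number 54 is absent. Of the 4484 genes in the table, 4465 had a gene symbol in GENCODE release M21, which also gave positions. Correlations between libraries are those of deviations from the group mean, which by itself draws values within a group below 0. Pairs of a group with the same animal number correlated about as much (mean -0.21, from -0.76 to 0.57 over 22 pairs) as pairs with another number (-0.24, from -0.89 to 0.76 over 94 pairs). That does not settle whether a repeated number is 1 animal. Each library was treated as its own animal. Within groups no pair of libraries was a resequenced copy, as the chi-square per degree of freedom of their reads was 4.17 or more over 116 pairs.

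Genes with at least 10 recovered reads in at least 4 libraries were tested, 4273 in all. Models were fitted to the deposited log2 values with limma 3.58.1 in R 4.3.3, with an intensity trend and a robust fit, and p-values were adjusted by Benjamini-Hochberg over all genes tested with a threshold of 0.05. A 24 h rhythm was the joint test of a cosine and a sine term with sex as a covariate, and the same test was run in males and females alone. The amplitude is from the mean to the peak, on the log2 scale, and the peak is in zeitgeber hours. The difference of rhythm between the sexes was the joint test of the sex by cosine and sex by sine terms. Males were compared with females with time as a factor, the light phase with the dark phase by equally weighted group means, and a 12 h rhythm by adding 12 h terms to the 24 h model. Genes called in both sexes were counted against chance with a one-sided Fisher exact test. The planned test was a count model, edgeR quasi-likelihood, which was not run. A test on the log2 scale of the deposited values was chosen instead, although the recovered reads would have allowed a count model. The recovered reads were tested with limma voom as an alternative, and the deposited scale took the place of TMM factors.

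The comparisons, their covariates, 29 gene lists with 451 genes and the rule for named genes were fixed before the data were examined. Of the listed genes 120 were in the table and 119 were tested, and 16 lists had at least 3 tested genes. Enrichment of rhythmic genes in a list was tested with a one-sided Fisher exact test against all other tested genes. The direction of a list was tested with camera at a preset correlation of 0.01, and both were adjusted by Benjamini-Hochberg over the lists. The genes named were every measured core clock gene, then the 10 called genes of largest amplitude outside that list with a peak from ZT0 to ZT12 and the 10 with a peak from ZT12 to ZT24, at a mean of at least 1 on the log2 CPM scale. To these were added up to 4 members of each other list with the smallest rhythm p, the called genes of the sex comparison with the same sign at all 6 times, the measured members of the lists of Y-linked and X-linked genes, the 5 genes of smallest p for the interaction, and the 5 largest changes in each direction between the light and dark phases. Predicted genes without a proper name were passed over, and some genes that these rules select are not reported here. Exonic bases shared with other genes were counted from the same annotation.

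Data of the same size were simulated with each gene drawn on its own, without the structure that the real libraries share. The figures that follow hold for such independent genes and may differ in the real data. The model for all libraries recovered 68% of 100 rhythms with an amplitude of 0.25 and 93% of 100 with 0.5, with 9 false calls. The model for males recovered 27% and 78%, with 3 false calls. The sex comparison recovered 89% of differences of 0.5 and 100% of differences of -1, with 6 false calls. The test of the difference in rhythm recovered 13% of 100 rhythms of males alone with an amplitude of 0.25 and 56% of 100 with 0.5, with 5 false calls.

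The alternatives were another estimate of the scale, scaling by library totals, no filter or a stricter filter, limma voom on the recovered reads, a replicate block, thresholds of 0.01 and 0.1, time as a factor, camera with an estimated correlation, fry, and leaving out each library in turn. A pseudocount of 8, a fit without trend or robustness, the first 2 principal components of 2953 genes with a mean log2 value above 8 as covariates, leaving out the libraries numbered 49 to 60, and removing a trend on gene length and GC content in each library were chosen after seeing the data. Single measures per library were tested with 100000 permutations. Intervals for shares of reads are 95% Wilson intervals, which cover counting error only. All 59 columns of the table were used.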

Results

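RNA was measured in homogenate medial prefrontal cortex of adult male and female C57BL/6J mice, a wild-type inbred strain, killed at 4 h intervals over 24 h. The 59 libraries fell into 12 groups of zeitgeber time by sex, at ZT2, ZT6, ZT10, ZT14, ZT18 and ZT22, with 5 libraries in every group except ZT10 females, which had 4. ZT0 is lights on by convention, and the times from ZT12 to ZT24 are called the dark phase here, although the labels do not give the light schedule. The table analysed held 4484 genes, of which 4273 were tested. It held 120 of the 451 genes of the lists fixed beforehand, so gene counts and enrichment speak only for genes in the table. The reads recovered from the deposited values came to between 6317420 and 13325019 per library, with a median of 9015221. The 6 most abundant noncoding genes, led by Gm42418 with a mean of 48.8% and Gm23935 with 24.0%, together took a median of 77.5% of a library's reads in the table. None of the 13 mitochondrial transcripts listed was in the table. These reads and shares are therefore those of the table and not of whole libraries. Their share ran from 61.2% in ZT14 female replicate 5 (95% Wilson interval 61.16 to 61.22) to 91.2% in ZT10 female replicate 3 (91.14 to 91.17). All other genes in the table shared between 1013139 and 4277345 reads per library. That noncoding share followed no detectable 24 h rhythm (permutation p = 0.994 over 59 libraries). The libraries with the serial numbers 49 to 60 in their titles stood apart on the first principal component, which held 52.4% of the variance, with a mean score of 16.8 ± 5.76 (SD, n = 11) against means from -6.38 to 0.91 in the 4 earlier runs of 12 numbers. The labels do not state that each library came from its own mouse, so the p-values measure the spread between these libraries.

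**Figure D1:**
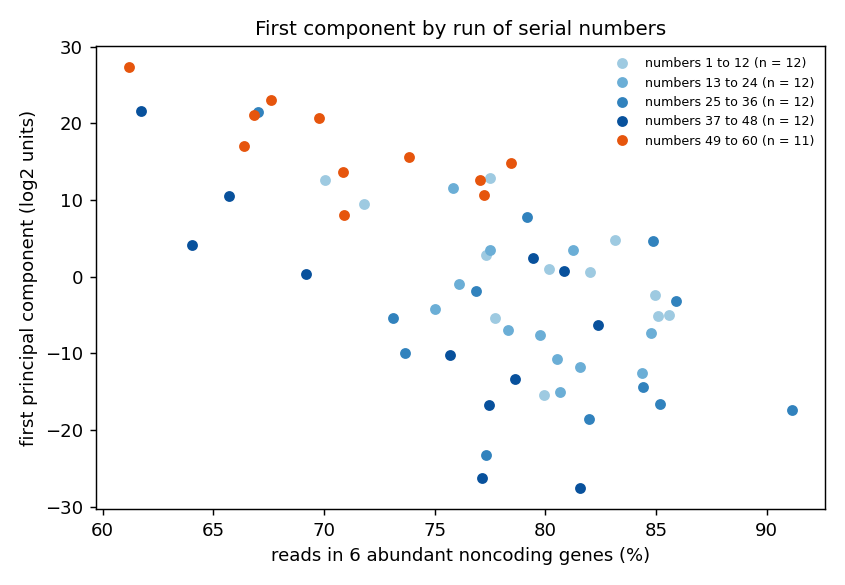
Score of each of the 59 libraries on the first principal component (vertical axis) against the share of its reads in the table taken by the 6 noncoding genes in percent (horizontal axis), with 1 point per library coloured by run of serial numbers. The 11 libraries numbered 49 to 60 had the highest mean score, 16.8.

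The first comparison asked which transcripts followed a 24 h rhythm, with both sexes fitted together. Of the 20 core clock genes listed, 7 were in the table and tested, and 6 of these passed. Members such as Clock and Dbp were not in the table. Per1, a clock repressor (ENSMUSG00000020893, chromosome 11, 69095217 to 69109960 in GRCm38), rose from a log2 value of 9.44 ± 0.35 (SD, n = 10) at ZT2 to 10.40 ± 0.39 (SD, n = 10) at ZT14. Its fitted amplitude, from the mean to the peak, was 0.45 ± 0.05 on the log2 scale (SE, n = 59), with the peak at ZT14.9. Per2 (ENSMUSG00000055866, chromosome 1, 91415982 to 91459324) had an amplitude of 0.52 ± 0.07 and peaked at ZT17.6, and Per3 had 0.23 ± 0.05 and peaked at ZT17.8. The nuclear receptor genes Nr1d1 and Nr1d2, which encode the REV-ERB repressors of the clock, came earlier. Nr1d1 (ENSMUSG00000020889, chromosome 11, 98767932 to 98775333) had an amplitude of 0.44 ± 0.08 with a peak at ZT11.6, rising from 9.32 ± 0.47 (SD, n = 10) at ZT2 to 10.20 ± 0.43 (SD, n = 9) at ZT10. Nr1d2 reached 0.24 ± 0.05 at ZT13.9. The transcription factor gene Hlf had an amplitude of 0.17 ± 0.04 and peaked at ZT19.8. Rora had an amplitude of 0.08 ± 0.06, with an adjusted p of 0.888 (limma, Benjamini-Hochberg). Among the 6 genes that passed, the adjusted p ran from 9.74e-08 for Per1 to 0.0271 for Hlf (limma, Benjamini-Hochberg). The list was enriched among rhythmic genes (one-sided Fisher exact test, adjusted p = 4.25e-09 by Benjamini-Hochberg over 16 lists), and 6 members also passed when adjusted over the list alone. The call for Hlf ended without ZT10 male replicate 3 (adjusted p = 0.0518, limma, Benjamini-Hochberg), ZT6 female replicate 4 (0.0513) or ZT10 female replicate 4 (0.0502), and without the libraries numbered 49 to 60 the calls for Hlf (0.108) and Per3 (0.187) both ended, which left 4 of the 7 members called. Without those libraries Hlf had an amplitude of 0.16 and Per3 of 0.19. Of Nr1d1, 263 of the 3077 exonic bases overlapped Thra on the other strand.

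Immediate early genes, which are transcribed within minutes of neuronal activity, were mostly highest in the dark phase. Arc, a regulator of synaptic strength (ENSMUSG00000022602, chromosome 15, 74669083 to 74672570), rose from 9.63 ± 0.22 (SD, n = 10) at ZT6 to 11.47 ± 0.45 (SD, n = 10) at ZT18. Its amplitude of 0.90 ± 0.07 (SE, n = 59) was the largest of all called genes and made a 3.5-fold range from trough to peak at ZT18.1. Fos (ENSMUSG00000021250, chromosome 12, 85473890 to 85477273) had an amplitude of 0.60 ± 0.10 and peaked at ZT17.9. Junb (ENSMUSG00000052837, chromosome 8, 84974484 to 84978718) had 0.48 ± 0.05 and peaked at ZT16.3. Egr1 reached 0.41 ± 0.09 at ZT19.5 and Jun 0.27 ± 0.04 at ZT20.2. Of the 10 tested members, 6 passed over all genes, each with a peak in the dark phase, and 8 when adjusted over the list alone. Among these 8, Nptx2 ran the other way, with an amplitude of 0.27 ± 0.08 and a peak at ZT5.14 (adjusted p = 0.168 over all genes, limma, Benjamini-Hochberg). The adjusted p was 6.02e-16 for Arc, 1.25e-08 for Junb, 0.000125 for Fos and for Jun and 0.0133 for Egr1 (limma, Benjamini-Hochberg). The list was enriched among rhythmic genes (one-sided Fisher exact test, adjusted p = 6.09e-08 by Benjamini-Hochberg).

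Of the genes induced by glucocorticoids, the 2 that passed peaked early in the dark phase. Tsc22d3, which encodes the glucocorticoid-induced leucine zipper protein (ENSMUSG00000031431, chromosome X, 140539528 to 140600659), rose from 9.78 ± 0.43 (SD, n = 10) at ZT6 to 10.65 ± 0.37 (SD, n = 10) at ZT14. Its amplitude was 0.44 ± 0.06 (SE, n = 59) with the peak at ZT15.8. Ddit4, which encodes an inhibitor of mTORC1 signalling, had an amplitude of 0.34 ± 0.08 and peaked at ZT16.1. Errfi1 had an amplitude of 0.14 ± 0.04 at ZT17.8 and Pdk4 of 0.23 ± 0.07 in another phase, at ZT1.12, with adjusted p of 0.139 and 0.184 (limma, Benjamini-Hochberg). Of the 5 tested members, 2 passed over all genes and 4, Pdk4 among them, when adjusted over the list alone. The list was enriched (one-sided Fisher exact test, adjusted p = 0.0137 by Benjamini-Hochberg).

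Chaperone genes of the endoplasmic reticulum that passed peaked late in the dark phase. Hspa5, which encodes the chaperone BiP (ENSMUSG00000026864, chromosome 2, 34771970 to 34777547), was lowest at ZT10, with 12.28 ± 0.16 (SD, n = 9), and highest at ZT18, with 12.97 ± 0.15 (SD, n = 10). Its amplitude was 0.29 ± 0.04 (SE, n = 59), with a fitted peak at ZT21.1. Pdia6, a protein disulphide isomerase gene, reached 0.22 ± 0.03 at ZT22.4, Manf reached 0.20 ± 0.03 at ZT21.9, and the co-chaperone gene Dnajc3 reached 0.16 ± 0.03 at ZT20.2. Of the 7 tested members, 4 passed over all genes and 7 when adjusted over the list alone. Among the latter Calr peaked after lights on, at ZT1.18, with 0.22 ± 0.07 (adjusted p = 0.169 over all genes, limma, Benjamini-Hochberg). Nptx2 and Calr were named after their values were seen. The adjusted p of these 4 genes ran from 9.88e-06 for Hspa5 to 0.0022 for Dnajc3 (limma, Benjamini-Hochberg), and the list was enriched (one-sided Fisher exact test, adjusted p = 2.14e-05). With a replicate block, or with the first 2 components as covariates, 7 members passed over all genes. Of the 9 heat shock chaperones, only Dnajb1 passed, also when adjusted over the list alone, with an amplitude of 0.14 ± 0.03 and a peak at ZT19.1. That list was not enriched (one-sided Fisher exact test, adjusted p = 0.399). The call for Dnajb1 (adjusted p = 0.0393, limma, Benjamini-Hochberg) ended without any 1 of 21 libraries, with an adjusted p of up to 0.0934, and without the libraries numbered 49 to 60 (0.0647).

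**Figure D2:**
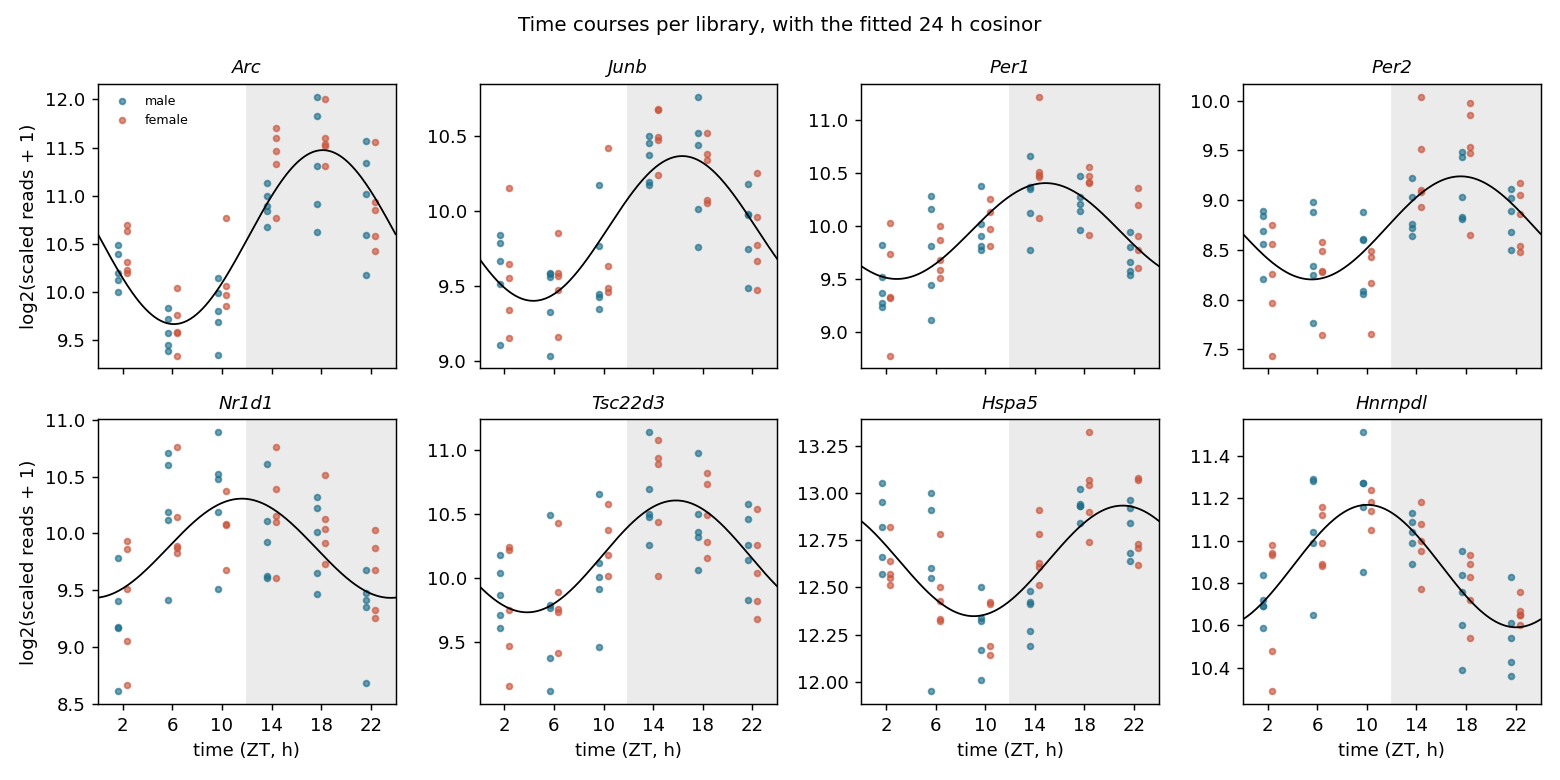
Deposited log2 values (vertical axes) against zeitgeber time in hours (horizontal axes) for 8 named genes, with 1 point per library coloured by sex, the fitted 24 h cosine in black and ZT12 to ZT24 shaded. The fitted curves of Arc, Junb, Per1, Per2 and Tsc22d3 peak from ZT14.9 to ZT18.1, that of Hspa5 at ZT21.1, and those of Hnrnpdl and Nr1d1 near the end of the light phase.

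Fewer genes peaked between ZT0 and ZT12. The splicing factor genes Hnrnpdl (ENSMUSG00000029328, chromosome 5, 100033577 to 100039664) and Tra2a peaked at ZT10.0 and ZT0.18, with amplitudes of 0.29 ± 0.03 and 0.20 ± 0.04 (SE, n = 59). Hmgcs1, which encodes the HMG-CoA synthase of cholesterol synthesis, had an amplitude of 0.13 ± 0.02 and peaked at ZT6.85. It was the 1 of 10 tested cholesterol genes that passed, also when adjusted over the list alone, and that list was not enriched (one-sided Fisher exact test, adjusted p = 0.399). The coenzyme A synthesis gene Ppcs reached 0.36 ± 0.09 at ZT5.13, Klhdc9 0.42 ± 0.10 at ZT6.44, Hs3st1 0.29 ± 0.07 at ZT5.04, Tpst2 0.23 ± 0.05 at ZT9.86 and Marc2 0.20 ± 0.04 at ZT10.8. Cyth4 (0.50 ± 0.11) and Vwc2l (0.28 ± 0.07) peaked soon after ZT0, at ZT0.83 and ZT0.36. The adjusted p of these genes ran from 3.80e-08 for Hnrnpdl to 0.0412 for Vwc2l (limma, Benjamini-Hochberg). The call ended without any 1 of 21 libraries for Vwc2l and of 10 for Ppcs, and for Klhdc9 without ZT18 female replicate 3 (adjusted p = 0.0616, limma, Benjamini-Hochberg) or ZT18 male replicate 1 (0.0598). Without the libraries numbered 49 to 60 the calls ended for Hmgcs1 and Cyth4 (adjusted p = 0.0503 for each, limma, Benjamini-Hochberg), Klhdc9 (0.0503), Hs3st1 (0.0521), Ppcs (0.0647) and Vwc2l (0.257). Their amplitudes there were of similar size, 0.12 for Hmgcs1, 0.53 for Cyth4, 0.48 for Klhdc9, 0.31 for Hs3st1, 0.40 for Ppcs and 0.25 for Vwc2l. Of the exonic bases of Klhdc9, 34.3% overlapped Pfdn2 on the other strand.

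Among the dark-phase genes outside these lists, the GTPase gene Arl4d reached 0.51 ± 0.09 (SE, n = 59) at ZT16.9, and the stress-response gene Gadd45b reached 0.50 ± 0.11 at ZT14.9. Zfp189 had an amplitude of 0.45 ± 0.08 at ZT15.9, Banp 0.45 ± 0.07 at ZT18.0 and Ier5l 0.42 ± 0.06 at ZT16.5. Without the libraries numbered 49 to 60 the call for Gadd45b ended (adjusted p = 0.0615, limma, Benjamini-Hochberg), with an amplitude of 0.51. Over all 4273 genes, 81 passed a Benjamini-Hochberg adjusted p of 0.05 in limma, and 486 had an unadjusted p under 0.05 against 214 expected by chance. Of the 81 genes, 60 peaked between ZT12 and ZT24 and 21 between ZT0 and ZT12. By 4 h bins from ZT0, 5, 8, 8, 13, 23 and 24 genes peaked. The amplitudes ran from 0.10 to 0.90 with a median of 0.22, and 6 genes changed at least 2-fold from trough to peak. Scaling by library totals alone, which the noncoding genes dominate, left 3 calls, Arc, Junb and Tsc22d3. Named genes that lost their call there kept amplitudes of similar size, such as Per1 with 0.43, Per2 with 0.52 and Hspa5 with 0.32. The first 2 principal components as covariates raised the count to 517 with all 81 among them. In the libraries numbered 1 to 48 alone 50 genes passed, 46 of them among the 81, and in the 11 libraries numbered 49 to 60 alone none passed (292 at an unadjusted p under 0.05, limma). Each of the 81 genes peaked in one part within 6 h of its peak in the other, against 65.9% of all genes. The 81 were called on both parts together. Of the 50 genes called in numbers 1 to 48 alone, 47 peaked within 6 h in numbers 49 to 60.

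**Figure D3:**
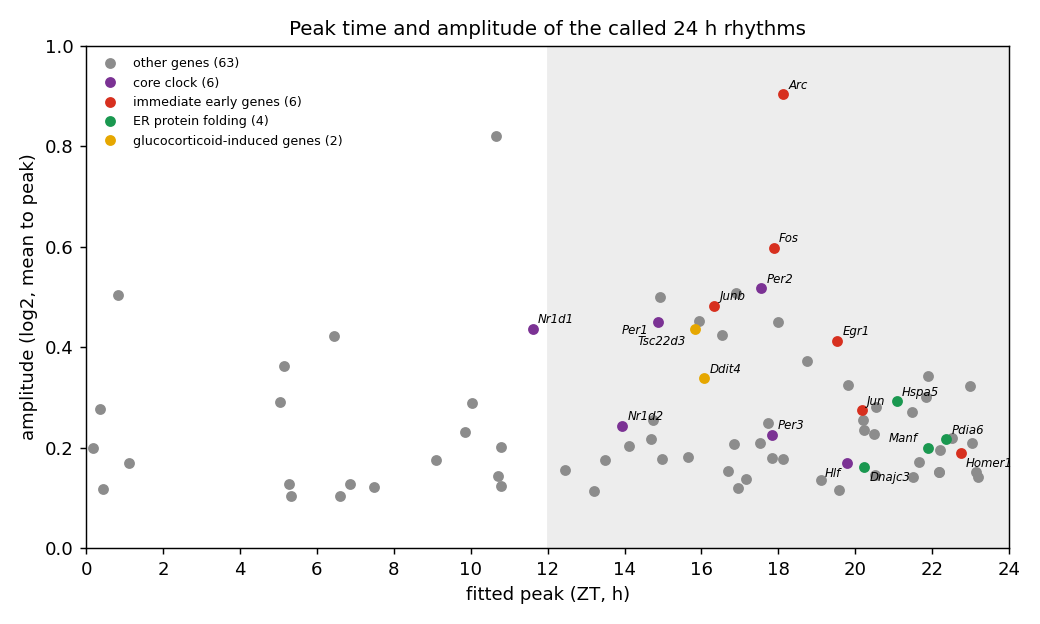
Fitted amplitude from mean to peak (vertical axis, log2) against fitted peak time (horizontal axis, zeitgeber hours) of the 81 genes with a 24 h rhythm, with 1 point per gene coloured by gene list and ZT12 to ZT24 shaded. Of these genes 60 lie in the shaded part, where Arc reaches the largest amplitude, 0.90.

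The other gene lists held few rhythmic members. In the list of monoamine and acetylcholine receptors 1 of 6 passed, the serotonin receptor gene Htr1b, with an amplitude of 0.22 ± 0.05 (SE, n = 59), a peak at ZT22.5 and an adjusted p of 0.0206 (limma, Benjamini-Hochberg), and it also passed when adjusted over the list alone. That list held no histamine receptor. Outside it the histamine receptor gene Hrh3, named after its values were seen, was called too, with an amplitude of 0.28 and a peak at ZT20.5. None passed among 15 nuclear respiratory chain genes, 11 cytosolic ribosomal protein genes, 5 ionotropic glutamate receptor genes, 3 GABA-A receptor genes, 2 interferon response genes or 3 X-inactivation and escape genes. Of these 39 genes, 0 were called by limma and 0 by limma voom, and 1 had an unadjusted p under 0.05 with either. That gene, Ddx3x, passed when adjusted over the list alone, with an amplitude of 0.13 ± 0.04. Among the markers of cell types, 0 of the 25 tested were called by limma or by limma voom and 4 had an unadjusted p under 0.05 with either tool. They included 5 markers of glutamatergic neurons, 8 of GABAergic neurons, 4 of astrocytes, 3 of microglia, 2 of striatal projection neurons and 1 each of oligodendrocyte precursors (C1ql1), leptomeningeal cells (Lum) and the olfactory bulb (Calb2, also a GABAergic marker). Adjusted over the list alone, 1 GABAergic marker passed, the corticotropin-releasing hormone gene Crh. Its amplitude was 0.44 ± 0.11 at ZT8.58, with an adjusted p of 0.0639 over all genes (limma, Benjamini-Hochberg). Adjusted over the list alone, 1 astrocyte marker, Fgfr3 (0.24 ± 0.07 at ZT19.9), passed too, with an adjusted p of 0.0961 over all genes (limma, Benjamini-Hochberg). Calb2 (0.16 ± 0.06 at ZT1.86) was the only tested olfactory bulb marker, so its pass there is an unadjusted one. It did not pass among the GABAergic markers or over all genes (adjusted p = 0.331, limma, Benjamini-Hochberg). Cold-inducible RNA-binding proteins, mitochondrial transcripts, Y-linked genes and markers of endothelial, choroid plexus and blood cells had no tested member.

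The next comparison asked whether males and females shared these rhythms, with each sex fitted alone. In males 7 genes passed (322 at an unadjusted p under 0.05, 214 expected) and in females 14 (380) with limma and a Benjamini-Hochberg adjusted p under 0.05. The 5 genes called in both were Arc, Per1, Junb, Hspa5 and Hnrnpdl, against 0.0229 expected of independent lists (one-sided Fisher exact test, p = 3.54e-12). Arc had an amplitude of 0.90 ± 0.09 (SE, n = 30) in males and 0.92 ± 0.09 (SE, n = 29) in females, with peaks at ZT18.6 and ZT17.7. Hspa5 had amplitudes of 0.31 ± 0.06 and 0.31 ± 0.05, with peaks at ZT22.4 in males and ZT19.7 in females. The remaining male calls were Pdia6 and Rasl10a, and the remaining female calls included Per2, Fos, Jun, Egr1, Tsc22d3, Banp, Ier5l and Dzip1l. Rasl10a and Dzip1l were named after their values were seen. All 7 male genes had an unadjusted p under 0.05 in females, and 11 of the 14 female genes had one in males. Of the 7 male genes, 7 peaked within 4 h in females, and of the 14 female genes 13 did in males, against 32.2% of all genes. Of the 81 genes called in both sexes together 79 did, with a median male to female amplitude ratio of 1.01, but a call on both sexes together favours genes whose peaks agree. The male count fell to 4 without ZT14 male replicate 5 and rose to 11 without ZT6 male replicate 4, ZT18 male replicate 5 or ZT22 male replicate 5, and the female count fell to 9 without ZT10 female replicate 3. Without the libraries numbered 49 to 60, 4 genes were called in males and 5 in females. With the first 2 components as covariates 130 were called in females, and in males 83 with a peak in the dark phase and 41 with one in the light phase. The number shared fell to 3 without ZT2 male replicate 5 or ZT14 male replicate 5, and to 1 under scaling by library totals alone or without the libraries numbered 49 to 60.

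A direct test of the difference in rhythm between the sexes called no gene. With limma 0 genes passed, 180 had an unadjusted p under 0.05 against 214 expected, and with limma voom 0 passed and 267 had one. With the runs of serial numbers as a replicate block 0 passed and 344 had one. Per2 had an amplitude of 0.33 ± 0.08 (SE, n = 30) in males and 0.72 ± 0.11 (SE, n = 29) in females, an unadjusted interaction p of 0.0132 and an adjusted p of 0.741 (limma, Benjamini-Hochberg). The named genes of smallest p included Adrb3, Trmt2b, Adck2 and Ift52, with unadjusted p from 0.000841 to 0.00418 and an adjusted p of 0.741 for each (limma, Benjamini-Hochberg). The beta-3 adrenoceptor gene Adrb3 had 0.50 ± 0.21 in males and 0.86 ± 0.25 in females, with peaks at ZT13.5 and ZT4.07. Trmt2b peaked at ZT9.63 in males and ZT2.47 in females, Adck2 at ZT21.5 and ZT6.96, and Ift52 at ZT10.8 and ZT4.23. On simulated data of independent genes with a rhythm in males alone this test recovered 56% of rhythms with an amplitude of 0.5 and 13% of those with 0.25.

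Levels of expression differed between males and females at 1 gene in the main fit. None of the 7 Y-linked genes listed was in the table, and 3 of the 11 X-inactivation and escape genes were tested, without Xist. Sex differences of the untested genes could therefore not be called. Ddx3x, an X-linked RNA helicase gene known to escape X inactivation (ENSMUSG00000000787, chromosome X, 13280970 to 13294052), had a mean log2 value of 12.33 ± 0.21 (SD, n = 30) in males and 12.63 ± 0.20 (SD, n = 29) in females. The difference, male minus female, was -0.30 ± 0.05 (SE) with the same sign at 6 of 6 times and an adjusted p of 0.000244 (limma, Benjamini-Hochberg). It was -0.31 in the libraries numbered 1 to 48 and -0.34 in those numbered 49 to 60. Kdm5c, a histone demethylase gene that also escapes (ENSMUSG00000025332, chromosome X, 152233020 to 152274535), had a difference of -0.41 ± 0.10 with the same sign at 6 of 6 times and an adjusted p of 0.213 over all genes (limma, Benjamini-Hochberg). It passed with the first 2 components as covariates (-0.36, adjusted p = 3.48e-09, limma, Benjamini-Hochberg), where 3 genes were called, and with the trend on length and GC removed (-0.38, 0.00122), where 2 were. With the runs of serial numbers as a replicate block it passed too, and 2 genes were called. The difference was -0.44 in the libraries numbered 1 to 48 and in those numbered 49 to 60. Utp14a had -0.01 ± 0.15. Adjusted over the list alone, 2 of these 3 tested X-linked genes passed, and the list was lower in males (camera, adjusted p = 4.67e-09, and adjusted p = 0.00158 with an estimated correlation). Immediate early genes as a list had a mean difference of -0.13, with 2 of 10 members above 0 (camera, adjusted p = 0.00244). That call was lost with an estimated correlation (adjusted p = 0.135). Of 100 splits that shuffled the sexes within each time, the real one included, 5 called at least 1 gene. Any call reaches a count of 1, so these splits bear on the count and not on the Ddx3x difference itself. The call for Ddx3x ended when libraries were scaled by their totals alone (-0.29, limma, Benjamini-Hochberg adjusted p = 0.9996).

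The mean of ZT2, ZT6 and ZT10 was then set against that of ZT14, ZT18 and ZT22. Activity and clock genes were lower in the light phase. Arc fell by 1.19 ± 0.09 (SE, n = 59) on the log2 scale, Fos by 0.77 ± 0.14, Arl4d by 0.72 ± 0.13, Per2 by 0.72 ± 0.10 and Ier5l by 0.62 ± 0.08. Among called genes, the 5 with the largest rise in the light phase changed less than these 5. Ppcs was higher by 0.50 ± 0.13, Arhgef15 by 0.33 ± 0.08, Gpr22 by 0.17 ± 0.04, Hmgcs1 by 0.16 ± 0.03 and the translation factor gene Eif5 by 0.15 ± 0.03. Of 30 genes called, 7 were higher in the light phase and 23 in the dark phase (limma, Benjamini-Hochberg adjusted p under 0.05), with an adjusted p of 8.80e-15 for Arc and 0.0426 for Gpr22. Core clock genes fell as a list (mean difference -0.27, 1 of 7 members above 0, camera, adjusted p = 1.32e-10), as did immediate early genes (-0.41, 1 of 10 above 0, adjusted p = 1.46e-14) and chaperones of the endoplasmic reticulum (-0.10, 1 of 7 above 0, adjusted p = 5.72e-05). These 3 calls held with an estimated correlation (adjusted p = 7.43e-05, 2.51e-05 and 0.00997). Glucocorticoid-induced genes had a mean difference of -0.15 (camera, adjusted p = 0.0122), with an adjusted p of 0.22 with an estimated correlation. Nuclear respiratory chain genes had a mean difference of 0.06, with 14 of 15 members above 0 (camera, adjusted p = 0.0309), with an adjusted p of 0.605 with an estimated correlation. Without the libraries numbered 49 to 60, 13 genes were called, none of them higher in the light phase, and scaling by library totals alone left 6, likewise. The calls for Ppcs, Arhgef15 and Gpr22 ended without any 1 of 22, 28 and 35 libraries.

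Times around dusk (ZT10 and ZT14) were compared with times around dawn (ZT22 and ZT2) for the lists alone. Core clock genes were higher around dusk, with a mean difference of 0.25 and 6 of 7 members above 0 (camera, adjusted p = 5.99e-05, and adjusted p = 0.0147 with an estimated correlation). Chaperones of the endoplasmic reticulum were lower around dusk, with a mean difference of -0.28 and 0 of 7 members above 0 (camera, adjusted p = 3.82e-17, and adjusted p = 5.98e-07 with an estimated correlation). Immediate early genes had a mean difference of -0.18 (camera, adjusted p = 0.0169) and heat shock chaperones of -0.10 (adjusted p = 0.0257). Both of these calls were lost with an estimated correlation (adjusted p = 0.214 for each). The median and the mean of a list differed in sign for astrocyte markers between the phases (0.03 and -0.004), for monoamine and acetylcholine receptors around dusk (0.001 and -0.09) and, between the sexes, for core clock genes (0.01 and -0.02), heat shock chaperones (0.01 and -0.04) and those receptors (0.01 and -0.0004), none of which passed.

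A 12 h rhythm on top of the 24 h rhythm was tested last, and no gene passed. Arc had an unadjusted p of 0.0276 and Hspa5 of 0.0122, both with an adjusted p of 0.624 (limma, Benjamini-Hochberg). With limma 0 genes were called and 291 had an unadjusted p under 0.05 against 214 expected, and with limma voom 0 were called and 280 had one. Without the libraries numbered 49 to 60, 0 were called and 567 had one, and with a replicate block 0 were called and 554 had one. Sampling at 4 h intervals gives 3 times per 12 h cycle.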

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

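The values examined in this part were those of some called genes and of measures per library, which were picked after results were seen. Of 96 groups of values examined for a single one far from the rest, 4 held one. Chance alone gives about 1 in 20 groups, so these are no more than chance would give. The log2 value of Fos was 6.43 in ZT10 male replicate 1, below the next lowest value of 7.50 at that time. In ZT14 female replicate 5 Fos reached 9.37, above the next highest value of 8.54. Hmgcs1 was 13.3 in ZT10 male replicate 3, where the next highest value was 13.14. The reads outside the 6 abundant noncoding genes came to 3980000 in ZT6 female replicate 4, against 2007000 in the next highest library of its group.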

How the results depend on the processing

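The settings chosen after the data were seen were the pseudocount, the fit without trend or robustness, the 2 components, the libraries numbered 49 to 60, and length and GC. The interaction and the 12 h rhythm had 0 calls under every setting run, and 4 lists stayed enriched for rhythmic genes under every setting run for them. Enrichment was not tested under scaling by library totals or with time as a factor. Under totals only Arc, Junb and Tsc22d3 were called, so no core clock gene and no chaperone gene of the endoplasmic reticulum was. Scaling by library totals gave 3 rhythmic genes in all libraries, 1 in males, 1 in females, 1 in both sexes, 0 for sex and 6 by phase. Totals follow the noncoding genes. A threshold of 0.01 gave 48, 4, 7 and 2 for the first 4 of these, and 0.1 gave about 1.3e+02 (87 peaking in the dark phase and 42 in the light phase), 17 and 22, and 50 by phase. Time as a factor gave 45, 2, 8 and 2, testing 5 terms. Leaving out the libraries numbered 49 to 60 gave 50, 4, 5 and 1, and 13 by phase (all higher in the dark), with fewer libraries. The 2 components gave 517 (301 peaking in the dark phase), about 1.2e+02 (83 and 41 in the dark and light phases), 130 and 39, with 3 for sex and 216 by phase (75 higher in the light), keeping all 81, 7 and 14 calls of the original fit. Removing length and GC gave 20 in males and 2 for sex, and kept 67 of the 81 calls in all libraries, 10 of the 14 in females and 23 of the 30 by phase, with 3 instead of 7 higher in the light. The cause was not tested for these. A replicate block, the runs of serial numbers, gave 82 peaking in the dark and 32 in the light phase, 15 in males, 8 in both, 2 for sex (Ddx3x and Kdm5c) and 46 by phase, and an unadjusted p under 0.05 for 344 genes in the interaction and 554 in the 12 h rhythm. In their deviations from the group means, libraries of a run correlated by -0.79 to 0.85 (mean 0.21, 60.5% of 319 pairs above 0.1, with means of 0.06 to 0.13 in the first 4 runs and 0.73 in numbers 49 to 60) and those of different runs by a mean of -0.05 (37.5% of 1276 pairs). Of 59 libraries 30 correlated best with one of their own run, a hint from the data that runs share something. Not every pair passed 0.1, and the main fit left the runs out, although 41.1% of the variance of the first component lay between them. Each run held 1 library of each group, save for the absent number, so the runs could serve as a block. The counts of the main fit are those without it. Camera with an estimated correlation and fry each gave 3 lists by phase, 2 by dusk and 1 by sex. Leaving out 1 library gave 74 to 96 genes in all libraries, 4 to 11 in males, 9 to 17 in females, 3 to 7 in both, 25 to 38 by phase and 1 for sex. Of 1378 values of named genes under other settings, 1279 kept their direction and their side of the threshold. Those reversed did not pass: Utp14a by sex (0.0051 by totals, 0.057 with 2 components, -0.056 to 0.045 without 1 library), and the amplitudes of Rpl3 (0.0085), Rpl13 (0.021) and Penk (0.040) with 2 components, and without 1 library of Rpl13 (0.0047 to 0.048) and Penk (0.0015 to 0.061). DESeq2, its calls in the list test and the legacy edgeR dispersion were not run. The recovered reads would have allowed them, and limma voom was the test run on those reads. At most 4277345 reads per library in the table outside the noncoding genes limit what genes of low expression can show.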

Other observations

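The tests of the RNA-binding protein families and of the first component in this part, the splits for all libraries with and without the 2 components, and the splits of the sexes within runs, were chosen after the result was seen. Of 25 tested genes of the RNA-binding and splicing families Hnrnp, Srsf, Tra2 and Rbm, 6 had a 24 h rhythm. The families were picked after called members were seen, so their number is not tested against other genes. Hnrnpdl peaked at ZT10.0 with an amplitude of 0.29 ± 0.03 (SE, n = 59) and Hnrnpc at ZT5.34 with 0.10 ± 0.03. Srsf10 peaked at ZT20.2 with 0.25 ± 0.06 and Srsf2 at ZT21.5 with 0.14 ± 0.03, Rbm5 peaked at ZT17.2 with 0.14 ± 0.03, and Tra2a close to ZT0 with 0.20 ± 0.04. They were named after their values were seen.

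The 6 genes did not share one phase, as the peaks of Hnrnpc and Rbm5 lay 11.83 ± 1.25 h apart (SE). The structure of the libraries along the first 2 components was not the whole cause of their calls, since with both as covariates all 6 passed. Removing the trend on gene length and GC left 5 of the 6, and it stays open for Hnrnpc (adjusted p = 0.169, limma, Benjamini-Hochberg). Leaving out the libraries numbered 49 to 60 left 3, without Srsf10 (0.0647), Rbm5 (0.0744) and Hnrnpc (0.212). Fewer libraries can end a call by themselves, so this count does not decide what part those libraries play. Overlap with other genes on the other strand stays open for Srsf2, where 15.6% of exonic bases overlapped Mettl23.

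The average time courses of the enriched lists were compared between the sexes by permuting sex within each time. Core clock genes had an amplitude of 0.19 in 30 males and 0.30 in 29 females (permutation p = 0.0954, Benjamini-Hochberg adjusted p = 0.191), and immediate early genes 0.31 and 0.37 (0.197, adjusted p = 0.263). Chaperones of the endoplasmic reticulum peaked at ZT22.9 in males and ZT21.2 in females (0.0681, adjusted p = 0.191), and glucocorticoid-induced genes at ZT17.9 and ZT16.0 (0.685, adjusted p = 0.685). None of the 4 differences passed, which does not show that the sexes were alike.

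Libraries of the same group were spread along the first component, which held 52.4% of the variance. Time of day and sex were not supported as its cause, as the 12 groups did not differ on it (permutation p = 0.761). Of its variance, 41.1% lay between the 5 runs of serial numbers (permutation p = 2e-05), and gene length and GC content accounted for 37.4% of the variance of the gene weights. It also fell with the share of the 6 noncoding genes within the libraries numbered 1 to 48 (Spearman rho -0.389, permutation p = 0.00667, adjusted 0.010, Pearson r -0.522, permutation p = 0.00013, adjusted 0.000195, and r -0.442 without the 2 farthest libraries) and within the 11 numbered 49 to 60 (rho -0.755, permutation p = 0.0102, adjusted 0.0102, r -0.744, permutation p = 0.00915, adjusted 0.00915, and r -0.655 without the 2 farthest). The component was itself built from genes that include Rpph1 and Rmrp of these 6, with weights of -0.049 and -0.047, among its most negative. Part of its fall with their share is therefore built in. A difference between runs, a length and GC bias or a varying share of noncoding reads may each be a source of this spread, and all 3 stay open.

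Splits of the libraries at random, 100 each with the real one, were used to ask whether chance could give as many calls. For the 24 h rhythm in all libraries 2 of 100 splits gave as many as the 81 real calls, the highest other giving 941. In females 3 gave as many as the real 14 (highest other 987), and in males only the real split reached its 7 (highest other 1). Only the real split reached the 30 genes by phase (1 of 100, highest other 1) and the 517 genes with 2 components (1 of 100, highest other 1). Each share was under 0.05, which makes chance an unlikely source of these counts. It does not exclude chance, as single random splits gave far more calls than the real one in all libraries and in females. These splits shuffled the times within each sex whatever the run. For sex 5 of 100 splits, which shuffled the sexes within each time whatever the run, called at least the 1 real gene (highest other 481). Any split with a call reaches a count of 1, so this count cannot tell the real split from chance, however large the difference of Ddx3x. Of these splits 3 called 481, 316 and 294 genes. Their shuffled sexes accounted for 12.7%, 8.38% and 8.39% of the first component within times, against 0.473% for the real sexes. By this share they ranked 1, 9 and 8 among the other splits. Some splits that followed the component more closely than those with 316 and 294 calls called no gene. With the runs of serial numbers as a replicate block and the sexes swapped within each time and run, 2 genes were called, Ddx3x and Kdm5c. As many were called in 2 of 100 splits, the real one included (highest other 4). That share is under 0.05, but this test was chosen after the result was seen, so chance is not excluded. For the interaction and the 12 h rhythm, with 0 real calls, all 100 splits reached as many, with highest others of 2 and 20. The splits that call many times the real count point to a structure of the samples.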
